A study of Mus musculus with 14 samples.

How the data were processed

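Total RNA of FACS-sorted osteoblasts and endothelial cells of mouse bone marrow was measured on 14 Affymetrix arrays. Per the labels, RNA was extracted with Trizol and biotinylated cRNA was prepared from 100 ng of it, and the cells were released by serial collagenase digestion. The deposited table of each array holds intensity values on a linear scale, 1 per probe set, which the authors made with Affymetrix Expression Console 1.1 per the labels, and their log2 was taken here. The algorithm that summarised the probes and its settings are not given in the sources used here. The 2%-trimmed means of the arrays, from 494.7 to 496.6, show that the deposited values had been scaled to a common level, so they were not normalised again.

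Each array has 45101 probe sets. The 64 control probe sets, 932 that the probe table gives several gene symbols and 9160 with no symbol were left out of the gene tests, which left 34945 with 1 symbol for 18193 symbols. Values were turned into log2 of intensity plus 16. Probe sets in the dimmest fraction of 0.333 by mean over all arrays were dropped, and of the rest the probe set with the highest mean stood for its gene, which left 13453 genes. The median log2 value of an array ran from 6.56 to 7.13. Correlation between arrays ran from 0.740 to 0.973. Genes are named by symbol, with the Entrez number of the probe table for those that open a comparison.

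Groups were taken from the labels: untreated and G-CSF osteoblasts (3 and 3 arrays) and untreated and G-CSF endothelial cells (4 and 4). A model with 4 group means was fitted to all arrays in limma 3.58.1 under R 4.3.3, with moderated variances that follow a trend in intensity. Contrasts were G-CSF against untreated in each population, the difference between these changes, and untreated osteoblasts against untreated endothelial cells. All p-values of genes are from this 2-sided limma test unless a sentence names another, adjusted by Benjamini and Hochberg over the 13453 genes, and a call means an adjusted p under 0.05. All values labelled camera are from limma's camera. In data with simulated changes of log2 size 1 and 2 in 100 genes, 20% and 88% were recovered in osteoblasts with 6 unchanged genes called, and 36% and 90% in endothelial cells with 8. With no simulated difference between the populations 0 genes were called as different. The simulated noise was independent for each gene and array. Shifts shared by many genes of an array were not simulated, so these rates may not hold for the real arrays.

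Gene lists, 35 in number with 609 genes of which 537 were measured, were written before the data were examined, as were the groups, the tests, the threshold, the rule for named genes and all alternatives but 5. They cover functions of osteoblasts, osteocytes and vessels, signalling pathways, cell states, and markers of other cell types of bone and marrow. Each was tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 35 lists of a comparison. The median and mean change of a list, and the counts of called members over all genes and adjusted over the list alone, describe its members. Named genes were, per comparison, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, up to 4 called members of a list or its 2 largest changes where none was called, and a fixed set of key genes. Genes outside this rule are said to be chosen after values were seen.

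Replicate numbers come from the titles, and the labels do not say what a number marks. Array deviations from their group mean correlated between untreated and G-CSF arrays of the same number by 0.223, 0.288 and 0.315 in osteoblasts and by 0.239, 0.377, 0.281 and 0.102 in endothelial cells, and each array correlated best with its own number. The numbers were therefore used as a block within each cell type as an alternative, with its values beside a result where they change a call or move a count by more than 1.5 times. Between the populations arrays of the same number correlated by -0.011 to 0.271. A block within each cell type cannot serve the contrast between cell types.

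Alternatives were pseudocounts of 1 and 64, quantile normalisation, centring on the median, no filter or dropping the lower 0.5 of probe sets, the mean of a gene's probe sets, probe sets without the suffix for cross-hybridisation, all probe sets singly, only the arrays compared, replicate blocks within and across cell types, array weights, a prior without trend or a robust one, a stricter threshold, an added minimum log2 change of 1, and each array left out in turn. Where that leaves 2 arrays in a group, the spread is pooled over all groups. After the data were seen 5 were added: without untreated osteoblast replicate 2 and untreated endothelial replicate 1, the number of decimals as a batch term, osteoblast replicates 2 and 3 alone, and the 3 prime to 5 prime ratio of actin or of GAPDH as a covariate. Osteoblast replicates 2 and 3 have 7 decimals in the table and the other arrays 1. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The changes of the populations were compared by the overlap of calls and by correlation across genes, with a jackknife over arrays.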

Results

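RNA of 2 stromal cell populations sorted from mouse bone marrow was measured on Affymetrix mouse arrays, with 1 array per sample and 14 arrays in all. The osteoblast population was GFP+ and lacked CD45, ter119 and CD31. It came from pOBcol2.3-GFP mice, in which a fragment of a type I collagen promoter marks osteoblasts with GFP. The endothelial population was CD31+ and lacked CD45, ter119 and GFP. The mice were C57BL/6J, 6 to 8 weeks old, and either untreated (vehicle alone, per the protocol text) or given 250 ug per kg of G-CSF, the cytokine that drives neutrophil production and releases blood stem cells from the marrow. The osteoblast groups held 3 untreated and 3 G-CSF arrays, and the endothelial groups held 4 and 4. The titles of the G-CSF arrays give 5 days of treatment, and so does their protocol text, while the protocol text of the untreated arrays gives 7 days. The labels do not say that replicates are separate animals, so every p-value measures only the spread between these samples. The number of arrays limits the precision of each value.

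The 2%-trimmed mean intensity lay between 494.7 and 496.6 on all 14 arrays. The median log2 value of all probe sets averaged 7.04 in untreated and 7.02 in G-CSF osteoblasts, 6.81 in untreated and 6.63 in G-CSF endothelial cells, so a scaling to equal medians moves every change by the difference between these values. The ratio of 3 prime to 5 prime actin signal, a sign of RNA quality, ran from 2.62 to 11.03, and osteoblast replicate 3 was highest in both osteoblast groups, at 11.03 untreated and 10.49 after G-CSF. The same ratio of GAPDH was highest in untreated endothelial replicate 1 (20.9, others of its group 9.61 to 13.5) and in osteoblast G-CSF replicates 2 (20.8) and 3 (18.4), against 8.43 to 12.96 in untreated osteoblasts, and lowest in osteoblast G-CSF replicate 1 (5.88). Of the arrays that stood apart by genes of other cell types, 2 were left out in an added alternative. In untreated osteoblast replicate 2 the neutrophil list averaged 12.81 on the log2 scale against 9.87 and 9.67 in the other untreated osteoblasts, the B lineage list 9.76 against 6.81 and 7.07, and the erythroid list 10.71 against 8.81 and 9.10. In untreated endothelial replicate 1 the skeletal muscle list averaged 13.43 against 7.74 to 9.33 in the other untreated endothelial arrays. Folds below are on the scale of log2 of intensity plus 16, which understates the change of genes with low signal. Errors of group means are SD and errors of changes are SE.

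**Figure D1:**
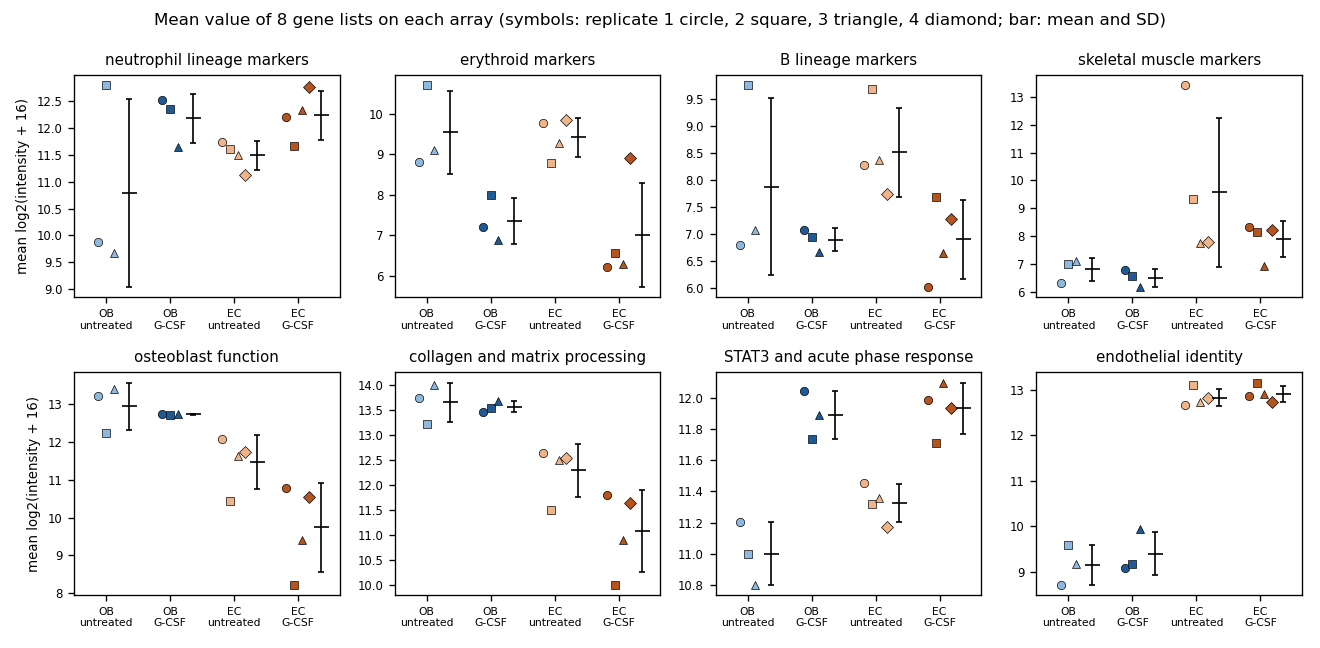
Mean log2(intensity + 16) of the measured members of 8 gene lists on each of the 14 arrays, by group, with 1 point per array, symbols for the replicate number, and a bar with whiskers for the mean and SD of the group. Untreated osteoblast replicate 2 stood at 12.81 for the neutrophil list and untreated endothelial replicate 1 at 13.43 for the skeletal muscle list, apart from the other arrays of their groups.

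The untreated populations were compared first, to see which genes mark each sort. All 27 measured genes of the endothelial identity list were lower in osteoblasts. Cdh5 (Entrez 12562), the cadherin of endothelial junctions, was 33.7-fold lower, at 8.80 ± 0.23 in 3 osteoblast arrays against 13.87 ± 0.14 in 4 endothelial arrays (adjusted p = 6.51e-09). The receptors Kdr and Tek, which bind VEGF and angiopoietins, were 17.7-fold (log2 change -4.14 ± 0.23) and 13.9-fold (log2 change -3.80 ± 0.22) lower, and Vwf, the clotting factor of endothelial granules, 33.1-fold (log2 change -5.05 ± 0.47) lower. Pecam1, which encodes CD31 itself, was 8.07-fold (log2 change -3.01 ± 0.30) lower. Thbs4 (Entrez 21828) and Ogn (Entrez 18295), matrix proteins of tendon and bone, were 52.3-fold (log2 change 5.71 ± 0.61) and 51.7-fold (log2 change 5.69 ± 0.32) higher in osteoblasts, and Postn, a matrix protein of periosteum, was 27.7-fold (log2 change 4.79 ± 0.60) higher.

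Some genes for bone matrix were higher in the osteoblast sort. Of the fixed key genes, Bglap, Spp1 and Runx2 were either not called or not measured in this comparison. Of the osteoblast list's 18 measured members, 7 were higher and 0 lower over all genes, and 7 and 0 adjusted over the list alone (camera adjusted p = 0.000936, and adjusted p = 0.597 with an estimated correlation). Omd, a keratan sulfate proteoglycan of bone, was 20.2-fold (log2 change 4.34 ± 0.68) higher, and Mmp13, a collagenase, 15.7-fold (log2 change 3.97 ± 0.58). Col1a1, the main collagen chain of bone, was abundant in both sorts, at 15.56 ± 0.51 in osteoblasts and 15.33 ± 0.38 in CD31+ cells (adjusted p = 0.814), and Sp7, an osteoblast transcription factor, read 11.43 ± 1.55 and 10.50 ± 0.92. Of the collagen list's 32 measured members, 13 were higher and 1 lower over all genes, and 13 and 1 adjusted over the list alone (camera adjusted p = 5.04e-06, and adjusted p = 0.563 with an estimated correlation). Of the Wnt list's 22 measured members, 12 were higher and 0 lower over all genes, and 13 and 0 adjusted over the list alone (camera adjusted p = 1.38e-06, and adjusted p = 0.133 with an estimated correlation), and Wnt16, a Wnt ligand that restrains osteoclasts, was 23.9-fold (log2 change 4.58 ± 0.44) higher. Among osteoclast regulators, of 10 measured members, 5 were higher and 2 lower over all genes, and 6 and 2 adjusted over the list alone (camera adjusted p = 0.0326, and adjusted p = 0.375 with an estimated correlation). Tnfsf11, the osteoclast-inducing ligand RANKL, was 17.8-fold (log2 change 4.15 ± 0.61) higher and its decoy receptor Tnfrsf11b 4.38-fold (log2 change 2.13 ± 0.66). Of the reticular stromal list's 16 measured members, 10 were higher and 0 lower over all genes, and 11 and 0 adjusted over the list alone (camera adjusted p = 6.58e-06, and adjusted p = 0.118 with an estimated correlation), and of the fibroblast and tendon list's 12 measured members, 4 were higher and 0 lower over all genes, and 6 and 0 adjusted over the list alone (camera adjusted p = 0.00151, and adjusted p = 0.352 with an estimated correlation).

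Vessel genes other than the identity list were lower in osteoblasts too. The identity list itself had camera adjusted p = 1.24e-32, and adjusted p = 0.0832 with an estimated correlation, with 27 members lower adjusted over the list alone. Of the sinusoidal list's 14 measured members, 1 was higher and 12 lower over all genes, and 1 and 12 adjusted over the list alone (camera adjusted p = 1.61e-07, and adjusted p = 0.134 with an estimated correlation). Of the arterial list's 13 measured members, 0 were higher and 7 lower over all genes, and 0 and 8 adjusted over the list alone (camera adjusted p = 5.32e-05, and adjusted p = 0.133 with an estimated correlation). Of the angiogenesis list's 19 measured members, 2 were higher and 9 lower over all genes, and 3 and 10 adjusted over the list alone (camera adjusted p = 8.92e-05, and adjusted p = 0.0967 with an estimated correlation). Of the interferon list's 27 measured members, 0 were higher and 16 lower over all genes, and 0 and 16 adjusted over the list alone (camera adjusted p = 2.16e-07, and adjusted p = 0.0832 with an estimated correlation). Of the endothelial activation list's 17 measured members, 1 was higher and 5 lower over all genes, and 2 and 5 adjusted over the list alone (camera adjusted p = 0.00706, and adjusted p = 0.257 with an estimated correlation). The skeletal muscle list had 6 of 11 members lower, 8 adjusted over the list alone, with Tnnc2 14.6-fold lower (camera adjusted p = 0.00295, and adjusted p = 0.597 with an estimated correlation), and untreated endothelial replicate 1 carried the highest muscle values. The adipocyte list had 5 of 8 lower, 6 adjusted over the list alone, among them the fatty acid transporter Cd36, 50.5-fold (log2 change -5.66 ± 0.32) lower (camera adjusted p = 0.000677, and adjusted p = 0.0967 with an estimated correlation).

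Niche factors went both ways between the untreated sorts. Of 19 measured members, 7 were higher and 3 lower in osteoblasts, 9 and 3 adjusted over the list alone (camera adjusted p = 0.0564). In the osteoclast marker list the median (0.02) and mean (0.06) were positive and the test pointed down (camera adjusted p = 0.786). Angpt1, a ligand of Tek, was 6.87-fold (log2 change 2.78 ± 0.32) higher in osteoblasts, and Il7, which B cell progenitors need, 6.19-fold (log2 change 2.63 ± 0.34) higher. Cxcl12, the chemokine that holds blood stem cells in the marrow, read 14.65 ± 0.25 in osteoblasts and 14.25 ± 0.19 in CD31+ cells (adjusted p = 0.132). Kitl, or stem cell factor, read 12.45 ± 0.86 and 12.43 ± 0.17, and Vcam1, an adhesion molecule for blood progenitors, 13.07 ± 0.37 and 13.52 ± 0.32. In total 1831 of 13453 genes were higher and 1722 lower in osteoblasts by limma, and 4940 had an unadjusted p under 0.05. The groups did not overlap for 32.6% of genes, against 5.71% by chance. After each array was centred on its median the split was 1239 higher and 2565 lower, 32.6% higher in place of 51.5%.

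Calls of 4 lists in the untreated comparison were lost when any 1 of several arrays was left out. The hypoxia list was lower with 5 of 18 members lower and 2 higher, 5 and 2 adjusted over the list alone (camera adjusted p = 0.0488, and adjusted p = 0.409 with an estimated correlation), but not without osteoblast replicate 1 (0.118) or 3 (0.114) or endothelial replicate 1 (0.0727). The megakaryocyte list was lower with 2 of 10 members, 2 adjusted over the list alone (camera adjusted p = 0.0488, and adjusted p = 0.643 with an estimated correlation), but not without osteoblast replicate 1 (0.126) or 3 (0.117) or endothelial replicate 2 (0.183). The oxidative phosphorylation list was lower with 3 of 21 members, 3 adjusted over the list alone (camera adjusted p = 0.0178, and adjusted p = 0.687 with an estimated correlation), but not without osteoblast replicate 1 (0.126) or endothelial replicate 1 (0.0772). The osteoclast regulators lost their call without the same arrays, at 0.0584 and 0.0554. Without osteoblast replicate 2, the array with high blood genes, the neutrophil list (1.95e-06), the monocyte list (4.31e-05) and the B lineage list (0.0108) were lower in osteoblasts, and the osteocyte list (0.0191) and niche factors (0.0108) higher. Niche factors also passed without endothelial replicate 2 (0.0443), and the pericyte list, lower, without endothelial replicate 3 (0.0428) or 4 (0.0367). Without osteoblast replicate 1 the STAT3 list (0.0448) and the immediate early list (0.0367) were lower and the cell cycle list higher (0.00439), and without osteoblast replicate 3 the cell cycle list was higher (0.008). Of 118 called genes named for this comparison 96 kept their call without any 1 array. Tnfrsf11b and Tnnc2 did not, with adjusted p of 0.115 and 0.0537 without osteoblast replicate 1, the highest for each. Over the arrays left out, the median differences of called lists that moved by over 1.5 times ranged from 0.73 to 1.89 for osteoblast, 0.91 to 1.87 for osteoclast regulator, -0.77 to -0.41 for endothelial activation and -0.76 to -0.23 for hypoxia genes. They ranged from -0.59 to -0.20 for oxidative phosphorylation, -1.84 to -0.74 for megakaryocyte and -3.79 to -1.63 for skeletal muscle genes.

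The next question was what G-CSF did to the osteoblast sort. Ifitm1 (Entrez 68713), an interferon-inducible membrane protein, rose 10.9-fold, from 10.87 ± 0.20 to 14.31 ± 0.68 (n = 3 and 3 arrays, adjusted p = 0.000258, limma). Stfa3 (Entrez 20863) and Stfa2l1, cysteine protease inhibitors of the stefin A family, rose 29.0-fold (log2 change 4.86 ± 0.70) and 15.0-fold (log2 change 3.91 ± 0.54). Saa3, an acute phase serum amyloid, rose 9.31-fold (log2 change 3.22 ± 0.56), Prok2, a secreted peptide of myeloid cells, 14.9-fold (log2 change 3.90 ± 0.55), and Wfdc17, a whey acidic protein family member of macrophages, 29.8-fold (log2 change 4.90 ± 0.84). Adipoq (Entrez 11450), or adiponectin, fell 4.96-fold (log2 change -2.31 ± 0.28), Cyp4b1, a cytochrome P450, 4.88-fold (log2 change -2.29 ± 0.32), and Apoe, a lipid carrier, 2.45-fold (log2 change -1.29 ± 0.21).

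Beyond these, Mgam, an enzyme that splits starch sugars, rose 17.1-fold (log2 change 4.09 ± 0.66), Asprv1, an aspartic protease, 13.0-fold (log2 change 3.70 ± 0.49), Ceacam10 12.4-fold (log2 change 3.63 ± 0.66) and Slfn4, a Schlafen family gene of myeloid cells, 8.52-fold (log2 change 3.09 ± 0.59). Pldi fell 4.28-fold (log2 change -2.10 ± 0.35), Tmem255a 4.02-fold (log2 change -2.01 ± 0.26) and Prkdc, a kinase of DNA repair, 2.23-fold (log2 change -1.16 ± 0.22). The call of Prkdc was lost with replicate numbers as a block (adjusted p = 0.0672). In all 25 genes rose and 6 fell, and 1191 of 13453 had an unadjusted p under 0.05. With the block 45 rose and 19 fell. With the osteoblast arrays fitted alone 2 rose and 0 fell, so 29 of the 31 calls ended, and a block across cell types kept 12 of the 31. All 31 called genes had groups that did not overlap, as had 9.29% of all genes, against 10% by chance. The counts turned on single arrays: 426 rose and 49 fell without untreated replicate 2, 8 rose without untreated replicate 1, 5 rose and 2 fell without untreated replicate 3, 2 rose and 2 fell without G-CSF replicate 1, and 6 rose and 3 fell without G-CSF replicate 2. Among the 17 called genes named for this comparison, 4 kept their call without any 1 array, namely Ifitm1, Asprv1, Adipoq and Tmem255a. Untreated replicates 1 and 3 and G-CSF replicates 1, 2 and 3 ended 8, 11, 13, 11 and 5 of the 17 calls when left out. The highest adjusted p without 1 array, with that array, was as follows: Wfdc17 (0.169, untreated 3), Stfa3 (0.0744, G-CSF 1), Mgam (0.14, untreated 3), Stfa2l1 (0.0654, G-CSF 1), Prok2 (0.0741, G-CSF 1), Ceacam10 (0.189, untreated 3), Saa3 (0.169, untreated 3), Slfn4 (0.221, untreated 3), Cyp4b1 (0.0666, untreated 3), Pldi (0.157, untreated 3), Apoe (0.0744, G-CSF 1), Prkdc (0.157, untreated 3) and Slc2a1 (0.169, untreated 3). The table prints osteoblast replicates 2 and 3 with more decimals than replicate 1. Among replicates 2 and 3 alone 2 genes rose and 1 fell, and replicate 1 alone, 1 array against 1, is too few for a test.

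Bone genes of the GFP+ sort showed no called change. Of the osteoblast list's 18 measured members, 0 rose and 0 fell over all genes, and 0 and 0 adjusted over the list alone (camera adjusted p = 0.423). Alpl, the alkaline phosphatase of mineralisation, had a log2 change of -0.83 ± 0.38 (adjusted p = 0.551), Col1a1 of 0.07 ± 0.60 and Sp7 of 0.03 ± 0.88. The collagen list's 32 measured members had a median change of -0.12 (camera adjusted p = 0.649), and the osteocyte list's 8 a median of 0.15 (camera adjusted p = 0.467). The niche factors had a median of -0.20 over 19 members, with 0 fallen over all genes and 1 adjusted over the list alone (camera adjusted p = 0.149). Cxcl12 went from 14.65 ± 0.25 to 14.10 ± 0.09 (adjusted p = 0.373), Il7 from 9.43 ± 0.89 to 7.83 ± 0.36 (adjusted p = 0.0947), with the block 0.0495, and Angpt1 from 9.09 ± 0.54 to 8.07 ± 0.36 (adjusted p = 0.336). Kitl, Vcam1 and Tnfsf11 had log2 changes of -0.54 ± 0.42, -0.52 ± 0.27 and 0.19 ± 0.66. Csf3r, the receptor of G-CSF, read 8.55 ± 1.38 and 10.42 ± 0.91 (adjusted p = 0.315). Without untreated replicate 2 the osteoblast list (0.034) and the niche factors (0.0031) fell, the latter also without G-CSF replicate 3 (0.0455).

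The list of STAT3 and acute phase genes rose as a group in the osteoblast arrays. The G-CSF receptor activates STAT3, but whether the rise came through it or with RNA of blood cells in the sort was not tested. Of the STAT3 list's 20 measured members, 1 rose and 0 fell over all genes, and 10 and 0 adjusted over the list alone, and its call held with both correlations (camera adjusted p = 3.77e-12, and adjusted p = 0.0231 with an estimated correlation). With the block 2 members rose, and the estimated correlation gave adjusted p = 0.216. The hypoxia and glycolysis list rose with Slc2a1, the main glucose transporter, up 2.67-fold (log2 change 1.42 ± 0.25) as the called gene of 18 measured, and 1 adjusted over the list alone (camera adjusted p = 9.82e-05, and adjusted p = 0.204 with an estimated correlation). The neutrophil list rose by a median of 1.20, with 0 of 20 members called over all genes and 12 adjusted over the list alone (camera adjusted p = 4.53e-13, and adjusted p = 0.303 with an estimated correlation). Ctsg, a granule protease of early neutrophils, had a log2 change of 2.79 ± 0.90 and Cxcr2, a chemokine receptor of late ones, of 2.53 ± 0.59. The erythroid list fell, at a median of -2.34, with 0 of 13 called over all genes and 13 adjusted over the list alone (camera adjusted p = 6.65e-13, and adjusted p = 0.28 with an estimated correlation). Klf1, the master regulator of red cell genes, had a log2 change of -2.91 ± 0.77 (adjusted p = 0.201), and 0.0332 with the block, the 1 erythroid gene then called, beside 1 neutrophil gene. The CD45 and ter119 gates remove those cells of these lineages that carry either marker, and cells with neither were not told apart here. Chosen after values were seen, S100a8, a calcium-binding protein of neutrophils, averaged 14.83 in untreated and 15.82 in G-CSF osteoblasts, and 15.37 and 15.32 in the endothelial sort. In untreated replicate 2 the neutrophil list averaged 12.81, above the 11.66 to 12.53 of the G-CSF osteoblasts.

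Several other lists were called in osteoblasts with the preset correlation alone. Of the monocyte list's 20 measured members, 0 rose and 0 fell over all genes, and 0 and 0 adjusted over the list alone (camera adjusted p = 1.92e-05, and adjusted p = 0.562 with an estimated correlation). Its median change was 0.96, 0.46 without untreated replicate 3 (camera adjusted p = 0.0556) and 1.85 without untreated replicate 2, where the list averaged 10.24 against 7.29 and 7.26. Of the reticular stromal list's 16 measured members, 0 rose and 1 fell over all genes, and 1 and 5 adjusted over the list alone, with Adipoq the called gene (camera adjusted p = 0.000192, and adjusted p = 0.303 with an estimated correlation). Of the adipocyte list's 8 measured members, 0 rose and 1 fell over all genes, and 0 and 2 adjusted over the list alone, again with Adipoq (camera adjusted p = 0.0281, and adjusted p = 0.303 with an estimated correlation), and with the block it was not called (0.0714). Of the B lineage list's 15 measured members, 0 rose and 0 fell over all genes, and 0 and 0 adjusted over the list alone (camera adjusted p = 0.00207, and adjusted p = 0.674 with an estimated correlation), and untreated replicate 2 alone carried the high B lineage value. The endothelial identity list had a median of 0.35 (camera adjusted p = 0.00372, and adjusted p = 0.722 with an estimated correlation), though Cdh5 and Kdr had log2 changes of 0.50 ± 0.25 and 0.21 ± 0.24 and 0 of 27 members were called, 0 adjusted over the list alone. The immediate early list had a median of 0.37 with 0 of 21 called and 0 adjusted over the list alone (camera adjusted p = 0.000301, and adjusted p = 0.562 with an estimated correlation). Of the unfolded protein response list's 23 measured members, 0 rose and 0 fell over all genes, and 1 and 0 adjusted over the list alone (camera adjusted p = 0.0306, and adjusted p = 0.39 with an estimated correlation). Of the fibroblast and tendon list's 12 measured members, 0 rose and 0 fell over all genes, and 0 and 0 adjusted over the list alone (camera adjusted p = 0.00955, and adjusted p = 0.562 with an estimated correlation). The interferon list was called with the block (0.0418) and not without it (0.0579), at a median of -0.29, and so was the pericyte list (0.0468 against 0.339), at a median of 0.51. With an estimated correlation the blocked adjusted p was 0.497 for interferon and 0.497 for pericyte genes. With the block Gadd45a, a growth arrest gene of the p53 list, rose (0.0151) and Col2a1, a collagen of cartilage, fell (0.0238). In 3 uncalled lists the median, mean and test differed in sign, namely Wnt (-0.00376, -0.01, up), BMP (0.03, -0.11, down) and sinusoidal (-0.09, 0.00508, up).

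Many of these osteoblast list calls were lost, and others gained, when 1 array was left out, given here as camera adjusted p without the array. Without untreated replicate 1 the endothelial identity (0.449, median 0.16), unfolded protein (0.069) and reticular (0.069) calls ended, and the MHC class II list fell (0.0319). That fall rested on untreated replicate 2, at 10.10 against 7.27 and 7.45, without which the median change was 0.66 (0.138). Without untreated replicate 2 the B lineage (0.778), immediate early (0.275), unfolded protein (0.43) and adipocyte (0.271) calls ended, and the cell cycle (1.57e-10) and oxidative phosphorylation (0.0172) lists rose. Without untreated replicate 3 the monocyte (0.0556) and fibroblast (0.0556) calls ended. Without G-CSF replicate 1 the unfolded protein call ended (0.0565) and the interferon list fell (0.0204). Without G-CSF replicate 2 the unfolded protein (0.0889), adipocyte (0.19) and fibroblast (0.149) calls ended, the interferon list fell (0.0467), and the angiogenesis (0.0137), endothelial activation (0.0329) and p53 (0.0161) lists rose. Without G-CSF replicate 3 the endothelial identity (0.883, median 0.07) and immediate early (0.106) calls ended and the cell cycle list rose (0.0248). With each array left out, the median changes of called lists that moved by over 1.5 times ranged from 0.86 to 2.48 for neutrophil, 0.46 to 1.85 for monocyte, -1.45 to -0.40 for B lineage and -0.74 to -0.17 for reticular genes. They ranged from -0.51 to -0.05 for adipocyte, 0.26 to 0.67 for fibroblast, 0.07 to 0.48 for endothelial identity, 0.16 to 0.65 for immediate early and 0.05 to 0.25 for unfolded protein genes. Medians of uncalled lists moved too, among them -0.51 to -0.07 for niche, -0.22 to 0.32 for osteocyte, -0.21 to 0.07 for collagen and -0.38 to -0.10 for interferon genes.

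In the endothelial sort G-CSF raised some of the same genes and lowered genes of the bone-forming lineage and of red cells. Ifitm1 (Entrez 68713) rose 20.7-fold, from 9.95 ± 0.46 to 14.32 ± 0.25 (n = 4 and 4 arrays, adjusted p = 1.38e-06, limma), Stfa3 31.3-fold (log2 change 4.97 ± 0.61) and Saa3 19.9-fold (log2 change 4.32 ± 0.48). Zbtb16 (Entrez 235320), a transcription factor that glucocorticoids induce in many tissues, rose 12.3-fold (log2 change 3.62 ± 0.43). Adipoq (Entrez 11450) fell 10.8-fold (log2 change -3.43 ± 0.24) and Vcam1 4.12-fold (log2 change -2.04 ± 0.24), from 13.52 ± 0.32 to 11.48 ± 0.46 (adjusted p = 0.00106). Il7 fell 2.75-fold (log2 change -1.46 ± 0.31), and Pth1r, the parathyroid hormone receptor of osteoblasts, 4.55-fold (log2 change -2.19 ± 0.52).

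With fold and log2 change in brackets, other large rises were Wfdc17 (15.8-fold, 3.98 ± 0.72), Stfa2l1 (12.8-fold, 3.68 ± 0.47), Prok2 (11.1-fold, 3.47 ± 0.48), Asprv1 (9.64-fold, 3.27 ± 0.43), Ms4a6d (9.13-fold, 3.19 ± 0.60) and Cd244a (8.63-fold, 3.11 ± 0.37). The other large falls were Ermap, an erythroid membrane protein (10.2-fold, -3.35 ± 0.66), Gng4 (9.75-fold, -3.28 ± 0.56), Prss35 (8.22-fold, -3.04 ± 0.71), Acaa1b (7.82-fold, -2.97 ± 0.40), Klf1 (7.71-fold, -2.95 ± 0.67), Oit3 (6.62-fold, -2.73 ± 0.48), Slit3 (5.97-fold, -2.58 ± 0.44), Podxl2 (5.87-fold, -2.55 ± 0.47) and Npy, a neuropeptide (5.86-fold, -2.55 ± 0.53). In all 61 genes rose and 154 fell, and 1765 of 13453 had an unadjusted p under 0.05. With replicate numbers as a block 139 rose and 521 fell. The groups did not overlap for 192 of the 215 called genes and for 10.3% of all genes, against 2.86% by chance. With each array centred on its median 81 rose and 54 fell, 60% rising in place of 28.4%. Leaving out untreated replicate 1 gave 15 up and 16 down, untreated replicate 3 gave 14 and 17, untreated replicate 4 gave 13 and 15, G-CSF replicate 2 gave 23 and 34 and G-CSF replicate 3 gave 38 and 80. Without untreated replicate 2, 323 fell, and 34 rose without G-CSF replicate 1 and 32 without G-CSF replicate 4. Among the 40 called genes named for this comparison, 11 kept their call without any 1 array: Stfa3, Ifitm1, Saa3, Stfa2l1, Zbtb16, Prok2, Asprv1, Cd244a, Adipoq, Acaa1b and Vcam1. Of the 40 calls, 28, 2, 28 and 29 ended without untreated replicates 1, 2, 3 and 4, and 9, 24, 22 and 9 without G-CSF replicates 1, 2, 3 and 4. The highest adjusted p without 1 array, with that array, was as follows: Wfdc17 (0.0624, untreated 4), Ms4a6d (0.0766, untreated 1), Ermap (0.0917, untreated 1), Gng4 (0.0661, untreated 3), Prss35 (0.16, untreated 3), Klf1 (0.14, untreated 1), Oit3 (0.0717, untreated 3), Slit3 (0.0661, untreated 3), Podxl2 (0.0866, untreated 1), Npy (0.108, untreated 1), Tnn (0.127, untreated 1), Cdh11 (0.124, untreated 1), Pth1r (0.173, untreated 1), Alpl (0.114, untreated 1), Col3a1 (0.111, untreated 1), Bgn (0.132, untreated 1), Il7 (0.117, untreated 1), Rspo3 (0.107, untreated 4), Bambi (0.128, untreated 1), Grem1 (0.143, untreated 1), Ccn2 (0.115, untreated 4), Cxcl9 (0.171, untreated 3), Hp (0.133, untreated 3), Pim1 (0.119, untreated 4), Bnip3 (0.148, untreated 3), Anxa1 (0.0538, untreated 4), Car1 (0.148, untreated 1), Kel (0.143, untreated 1) and Pdgfra (0.104, untreated 1).

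**Figure D2:**
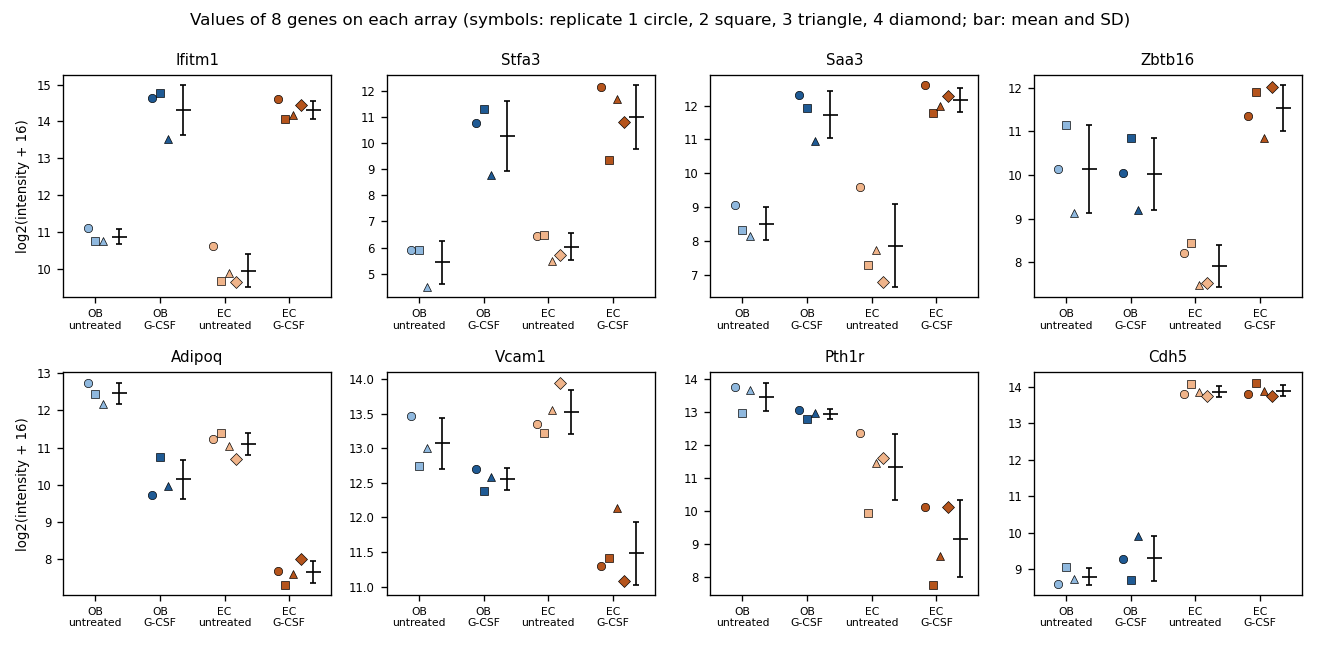
Log2(intensity + 16) of 8 genes on each of the 14 arrays, by group, with 1 point per array, symbols for the replicate number, and a bar with whiskers for the mean and SD of the group. Ifitm1 averaged 14.31 in G-CSF osteoblasts and 14.32 in G-CSF endothelial cells, and Zbtb16 rose from 7.91 to 11.53 in the endothelial arrays.

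Bone-lineage genes fell in the CD31+ arrays. Of the osteoblast list's 18 measured members, 0 rose and 4 fell over all genes, and 0 and 17 adjusted over the list alone, and 14 fell with the block, at a median of -2.05 (camera adjusted p = 1.46e-12, and adjusted p = 0.24 with an estimated correlation). Tnn, a matrix tenascin, fell 5.05-fold (log2 change -2.34 ± 0.52), Cdh11, the osteoblast cadherin, 4.94-fold (log2 change -2.31 ± 0.49), and Alpl 3.01-fold (log2 change -1.59 ± 0.33). Col1a1 read 15.33 ± 0.38 and 13.96 ± 1.49 (adjusted p = 0.242), and Sp7 10.50 ± 0.92 and 8.26 ± 1.71 (adjusted p = 0.166), with the block 0.0282. Of the collagen list's 32 measured members, 0 rose and 2 fell over all genes, and 0 and 22 adjusted over the list alone, and 20 fell with the block (camera adjusted p = 3.51e-14, and adjusted p = 0.24 with an estimated correlation). Col3a1, a fibrillar collagen, fell 3.17-fold (log2 change -1.67 ± 0.34) and Bgn, a small matrix proteoglycan, 2.77-fold (log2 change -1.47 ± 0.32). Of the osteocyte list's 8 measured members, 0 rose and 0 fell over all genes, and 0 and 4 adjusted over the list alone, and 4 fell with the block, Phex (0.0468) and Irx5 (0.0029) among them (camera adjusted p = 0.0114, and adjusted p = 0.521 with an estimated correlation). Of the Wnt list's 22 measured members, 0 rose and 1 fell over all genes, and 1 and 9 adjusted over the list alone, and 7 fell with the block (camera adjusted p = 8.84e-07, and adjusted p = 0.212 with an estimated correlation), and Rspo3, which strengthens Wnt signals, fell 2.68-fold (log2 change -1.42 ± 0.29). Of the BMP and TGF-beta list's 21 measured members, 0 rose and 3 fell over all genes, and 0 and 4 adjusted over the list alone (camera adjusted p = 0.00494, and adjusted p = 0.24 with an estimated correlation). Those that fell were Bambi and Grem1, which restrain these pathways, and Ccn2, a matrix protein that TGF-beta induces, by 2.79-fold (log2 change -1.48 ± 0.32), 2.19-fold (log2 change -1.13 ± 0.26) and 2.09-fold (log2 change -1.06 ± 0.24), and Grem1 was not called with the block (0.0563). The chondrocyte list had 0 of 14 members fallen, 0 adjusted over the list alone and 2 with the block, namely Col11a2 (0.00661) and Col2a1 (0.0102), collagens of cartilage (camera adjusted p = 0.391).

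Niche genes fell in part in the CD31+ arrays. Il7 was higher in the untreated osteoblast sort than in the CD31+ sort. Whether Il7 and the reticular genes below fell with RNA of the osteoblast lineage in the CD31+ sort was not tested. Of the niche list's 19 measured members, 0 rose and 2 fell over all genes, and 0 and 6 adjusted over the list alone, and 4 fell with the block (camera adjusted p = 0.0185, and adjusted p = 0.478 with an estimated correlation), and the called genes were Vcam1 and Il7. Cxcl12 read 14.25 ± 0.19 and 13.77 ± 0.28 (adjusted p = 0.198), with the block 0.0344, and Kitl 12.43 ± 0.17 and 12.69 ± 0.77 (adjusted p = 0.871). Of the reticular stromal list's 16 measured members, 1 rose and 4 fell over all genes, and 2 and 6 adjusted over the list alone (camera adjusted p = 0.000756, and adjusted p = 0.24 with an estimated correlation). There Adipoq, Vcam1, Grem1 and Pdgfra, a mesenchymal growth factor receptor down 4.86-fold (log2 change -2.28 ± 0.45), fell, and Hp, or haptoglobin, rose 2.35-fold (log2 change 1.23 ± 0.28). Of the fibroblast and tendon list's 12 measured members, 0 rose and 0 fell over all genes, and 1 and 2 adjusted over the list alone (camera adjusted p = 0.0136, and adjusted p = 0.478 with an estimated correlation), and 2 fell with the block, Dcn among them (0.0101). The adipocyte list had 1 of 8 fallen, Adipoq, and 2 adjusted over the list alone (camera adjusted p = 0.0925), with 2 fallen with the block. The pericyte list was not called (0.285) but was with the block (0.046), at a median of -0.35 over 11 members. The blocked adjusted p was 0.442 with an estimated correlation. The Schwann cell list's 4 members had a median of -0.35 (camera adjusted p = 0.216), and S100b was called with the block (0.0229).

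Genes that define vessels showed small differences. Cdh5 read 13.87 ± 0.14 untreated and 13.90 ± 0.16 after G-CSF, Tek 12.76 ± 0.16 and 12.80 ± 0.17, Kdr 14.03 ± 0.16 and 13.66 ± 0.05, and Pecam1 9.72 ± 0.47 and 10.15 ± 0.27, with adjusted p of 0.98, 0.972, 0.533 and 0.616. Of the endothelial identity list's 27 measured members, 0 rose and 0 fell over all genes, and 0 and 0 adjusted over the list alone, at a median of 0.04 (camera adjusted p = 0.124), and Sox7 was called with the block (0.0436). The arterial list had a median of 0.08 over 13 members (camera adjusted p = 0.492). The angiogenesis list had a median of -0.03 and a mean of -0.04 with the test pointing up (camera adjusted p = 0.75). Of the sinusoidal list's 14 measured members, 0 rose and 1 fell over all genes, and 0 and 2 adjusted over the list alone, Vcam1 being the called gene, and 2 fell with the block (camera adjusted p = 0.0264, and adjusted p = 0.542 with an estimated correlation). Of the endothelial activation list's 17 measured members, 0 rose and 2 fell over all genes, and 0 and 2 adjusted over the list alone (camera adjusted p = 0.725), namely Vcam1 and the chemokine Cxcl9, down 2.08-fold (log2 change -1.06 ± 0.25). Of the MHC class II list's 7 measured members, 0 rose and 0 fell over all genes, and 0 and 0 adjusted over the list alone, at a median of -1.14 (camera adjusted p = 0.0356, and adjusted p = 0.542 with an estimated correlation), and the chaperone Cd74 had a log2 change of -1.29 ± 0.75. The interferon list's 27 members had a median of -0.15 (camera adjusted p = 0.545). With each array centred on its median the medians of the angiogenesis, endothelial activation and interferon lists were positive.

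The list of STAT3 and acute phase genes rose in the endothelial sort too, and whether through the G-CSF receptor was not tested. Of the STAT3 list's 20 measured members, 3 rose and 0 fell over all genes, and 7 and 0 adjusted over the list alone, and 6 rose with the block (camera adjusted p = 1.08e-07, and adjusted p = 0.122 with an estimated correlation). These were Saa3, Hp and Pim1, a kinase that cytokines induce, up 2.18-fold (log2 change 1.12 ± 0.24). Csf3r read 9.54 ± 0.78 and 11.20 ± 0.48 (adjusted p = 0.142). Of the hypoxia list's 18 measured members, 1 rose and 0 fell over all genes, and 1 and 0 adjusted over the list alone (camera adjusted p = 0.000425, and adjusted p = 0.212 with an estimated correlation), with Bnip3, a mitophagy gene, up 1.95-fold (log2 change 0.96 ± 0.22). Of the p53 and apoptosis list's 17 measured members, 0 rose and 0 fell over all genes, and 0 and 0 adjusted over the list alone, and 2 rose with the block, Fas, a death receptor, among them (0.0377) (camera adjusted p = 0.0356, and adjusted p = 0.245 with an estimated correlation). The cell cycle list's 31 members had a median of 0.09 (camera adjusted p = 0.239) and the immediate early list's 21 a median of 0.10 (0.285). In 4 further uncalled lists the median, mean and test differed in sign. These were the unfolded protein response (0.09, -0.05, up, camera adjusted p = 0.492), oxidative phosphorylation (-0.04, -0.05, up, 0.947), osteoclast regulators (-0.22, -0.01, up, 0.725) and osteoclast markers (-0.04, -0.28, up, 0.676). With each array centred on its median the medians of the oxidative phosphorylation and osteoclast marker lists were positive. With the block Creb3l1 fell (0.00456), a secretory pathway factor of osteoblasts, as did Car2 (0.00668) and Ctsk (0.00766), enzymes by which osteoclasts resorb bone, and Sema3a, which protects bone from resorption, rose (0.0134).

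Blood cell lists moved in the endothelial sort as well, although its gates remove CD45+ and ter119+ cells. Of the erythroid list's 13 measured members, 0 rose and 6 fell over all genes, and 0 and 12 adjusted over the list alone, and 11 fell with the block, at a median of -2.52 (camera adjusted p = 7.62e-13, and adjusted p = 0.212 with an estimated correlation). Car1, a carbonic anhydrase of red cells, had a log2 change of -3.33 ± 0.79 and Kel, a red cell antigen, of -2.60 ± 0.58, and both fell. Of the B lineage list's 15 measured members, 0 rose and 0 fell over all genes, and 0 and 10 adjusted over the list alone, at a median of -1.90, and 3 fell with the block (camera adjusted p = 6.6e-06, and adjusted p = 0.425 with an estimated correlation), with Vpreb1, part of the pre-B cell receptor, called with the block (0.0154). Of the neutrophil list's 20 measured members, 1 rose and 0 fell over all genes, and 1 and 0 adjusted over the list alone, at a median of 0.66 (camera adjusted p = 5.96e-06, and adjusted p = 0.481 with an estimated correlation), and the called gene was Anxa1, up 2.02-fold (log2 change 1.01 ± 0.18). Of the monocyte list's 20 measured members, 0 rose and 0 fell over all genes, and 2 and 0 adjusted over the list alone (camera adjusted p = 0.0408, and adjusted p = 0.8291 with an estimated correlation), and with the block it was not called (0.0555). Cd14, a receptor for bacterial lipopolysaccharide, had a log2 change of 2.10 ± 0.56 (adjusted p = 0.0781). The megakaryocyte list's 10 members had a median of -0.32 (camera adjusted p = 0.492) and the T and NK cell list's 5 a median of -0.42 (0.636). The skeletal muscle list fell, at a median of -1.70, with 0 of 11 members called and 0 adjusted over the list alone (camera adjusted p = 0.00142, and adjusted p = 0.542 with an estimated correlation), and this call ended without untreated replicate 1, the array with high muscle genes (0.24), where the median was -0.54.

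Other endothelial list calls that turned on 1 array are given here as camera adjusted p without it. Without untreated replicate 2, the lowest untreated array for collagen genes at 11.50, the calls of niche factors (0.059), sinusoidal (0.0982), MHC class II (0.115), p53 (0.135) and monocyte (0.0553) genes ended, the chondrocyte list fell (0.00594) and the endothelial identity list rose (0.0198). Without untreated replicate 3 the sinusoidal call ended (0.0745), and without untreated replicate 4 the monocyte call ended (0.267) and the immediate early list rose (0.0464). Without G-CSF replicate 1 the p53 (0.0728), monocyte (0.0539), sinusoidal (0.105) and MHC class II (0.0977) calls ended and the adipocyte list fell (0.0405), so that 3 lists rose in place of 5. Without G-CSF replicate 2 the osteocyte (0.0567), fibroblast (0.063) and MHC class II (0.0788) calls ended, the adipocyte (0.0445) and pericyte (0.0445) lists fell and the cell cycle list rose (0.0178). Without G-CSF replicate 3 the osteocyte (0.0556) and monocyte (0.155) calls ended and the immediate early list rose (0.0235). Without G-CSF replicate 4, the highest G-CSF array for erythroid genes at 8.91, the monocyte (0.0613) and sinusoidal (0.199) calls ended, the endothelial identity list rose (0.0268) and the chondrocyte list fell (0.0192). With each array left out, the median changes of called lists that moved by over 1.5 times ranged from -2.32 to -0.54 for skeletal muscle, -0.49 to -0.22 for niche, -0.63 to -0.18 for sinusoidal, 0.06 to 0.18 for p53 and 0.07 to 0.55 for monocyte genes. Medians of uncalled lists are not ranged here.

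The last comparison asked whether the populations responded differently, as the change in osteoblasts minus the change in endothelial cells. The osteoblast list's median difference was 1.59 over 18 members (camera adjusted p = 9.13e-09, and adjusted p = 0.842 with an estimated correlation), with log2 changes of Alpl of -0.83 ± 0.38 in osteoblasts and -1.59 ± 0.33 in CD31+ cells. The collagen list differed by a median of 1.04 (camera adjusted p = 8.87e-11, and adjusted p = 0.842 with an estimated correlation), the Wnt list by 1.04 (camera adjusted p = 2.92e-06, and adjusted p = 0.487 with an estimated correlation) and the osteocyte list by 1.39 (camera adjusted p = 0.0022, and adjusted p = 0.907 with an estimated correlation). The fibroblast and tendon list differed by 1.13 (camera adjusted p = 5.88e-06, and adjusted p = 0.487 with an estimated correlation), with Dcn at -2.48 ± 0.70 in CD31+ cells and Thbs4 at 1.24 ± 0.65 in osteoblasts. The neutrophil list differed by 0.68 (camera adjusted p = 0.0147, and adjusted p = 0.95 with an estimated correlation), the sinusoidal list by 0.53 (camera adjusted p = 0.0301, and adjusted p = 0.907 with an estimated correlation), the immediate early list by 0.29 (camera adjusted p = 0.0452, and adjusted p = 0.95 with an estimated correlation) and the skeletal muscle list by 1.61 (camera adjusted p = 0.0301, and adjusted p = 0.95 with an estimated correlation). In these 9 lists 0 members passed over all genes, and adjusted over the list alone 1 sinusoidal and 1 fibroblast gene did. The erythroid list differed by a median of 0.19 (camera adjusted p = 0.941) and the STAT3 list by 0.25 (0.228). With the block the monocyte (0.0474 against 0.0809) and pericyte (0.00197 against 0.0879) lists differed too. They did not with an estimated correlation (blocked adjusted p = 0.84 and 0.27). In 5 uncalled lists the median, mean and test differed in sign, namely niche factors (-0.10, 0.27, up), osteoclast regulators (-0.01, 0.14, down), arterial (0.08, 0.0967, down), p53 (0.06, -0.04, down) and adipocyte (-0.13, 0.15, up).

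No single gene passed the test of the difference: limma called 0 of 13453, with 622 at an unadjusted p under 0.05, and 1 lower with the block. Without osteoblast untreated replicate 2, 18 were higher and 3 lower, without osteoblast untreated replicate 3, 1 was lower, and without endothelial G-CSF replicate 1, 1 was higher. Zbtb16 had a log2 change of -0.10 in osteoblasts and 3.62 ± 0.43 in CD31+ cells, with adjusted p = 0.208 for the difference. Some list differences also ended when 1 array was left out (camera adjusted p without each), and the smallest median left was 0.75 for osteocyte, 0.20 for neutrophil, 0.28 for sinusoidal, 0.08 for immediate early and 0.32 for skeletal muscle genes. The osteocyte difference ended without osteoblast untreated replicate 2 (0.248) or G-CSF replicate 1 (0.0841). The neutrophil difference ended without osteoblast untreated replicate 1 (0.43) or 3 (0.906), osteoblast G-CSF replicate 1 (0.3) or endothelial untreated or G-CSF replicate 2 (0.0701, 0.0756). The sinusoidal difference ended without osteoblast untreated replicate 1 (0.145) or 3 (0.0795), osteoblast G-CSF replicate 3 (0.287), endothelial untreated replicate 2 (0.103) or 3 (0.0763) or endothelial G-CSF replicate 1 (0.109) or 4 (0.188). The immediate early difference ended without osteoblast untreated replicate 2 (0.787) or 3 (0.118), osteoblast G-CSF replicate 1 (0.2) or 3 (0.633), endothelial untreated replicate 2 (0.0701) or 4 (0.213) or endothelial G-CSF replicate 3 (0.412). The skeletal muscle difference ended without any osteoblast untreated array (0.107, 0.0556, 0.0595), osteoblast G-CSF replicate 1 (0.2), endothelial untreated replicate 1 (0.881) or 2 (0.0582) or endothelial G-CSF replicate 3 (0.194). The osteoblast, collagen, Wnt and fibroblast differences held without each of the 14 arrays.

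Further lists differed between the populations with 1 array left out, all with a higher change in osteoblasts. Without osteoblast untreated replicate 2, the array with high blood genes, 15 lists differed in place of 9. Those gained were B lineage (5.13e-05), monocyte (6.56e-15), MHC class II (5.94e-05), cell cycle (3.37e-08), endothelial identity (0.0114), hypoxia (0.0382), oxidative phosphorylation (0.0138), megakaryocyte (0.0339) and T and NK cell (0.0138) genes. The count was 5 without osteoblast untreated replicate 3, osteoblast G-CSF replicate 1 or endothelial untreated replicate 2. STAT3 genes differed without osteoblast untreated replicate 1 (0.0194) or G-CSF replicate 2 (0.0389). Without the latter the endothelial identity (0.0161), angiogenesis (0.0315) and endothelial activation (0.0137) lists differed too. Monocyte genes differed without osteoblast G-CSF replicate 3 (0.00203) or endothelial untreated replicate 4 (0.00518), and erythroid genes without endothelial G-CSF replicate 4 (0.0029). Pericyte genes differed without osteoblast G-CSF replicate 3 (0.0373), endothelial untreated replicate 3 (0.024) or 4 (0.0255) or endothelial G-CSF replicate 1 (0.0348) or 2 (0.00995).

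The genes called in the populations overlapped. Of the 25 genes that rose in osteoblasts, 15 also rose among the 61 of the endothelial sort, against 0.113 for independent lists: Ada, Asprv1, Cd300lf, Cmah, Ifitm1, Il1r2, Klra17, Myd88, Prok2, Saa3, Slfn4, Spint1, Stfa2l1, Stfa3 and Wfdc17. Adipoq was the 1 gene that fell in both, of 6 and 154, against 0.0687. All 25 genes that rose in osteoblasts had a positive change in endothelial cells, and 51 of the 61 that rose there were positive in osteoblasts. Of the genes that fell, 4 of 6 and 127 of 154 shared their sign. Across all 13453 genes the log2 changes correlated with r = 0.494 (jackknife SE over arrays 0.151) and rho = 0.361, and 62.4% had the same sign. Genes are not independent replicates, so this is given across genes with no p. The values 0.113 and 0.0687 assume independent lists. Genes vary together, and the sorts may share animals or RNA of blood cells, so these values do not measure chance. With osteoblast replicates 2 and 3 alone r was 0.336, and replicate 1 alone is too few.

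**Figure D3:**
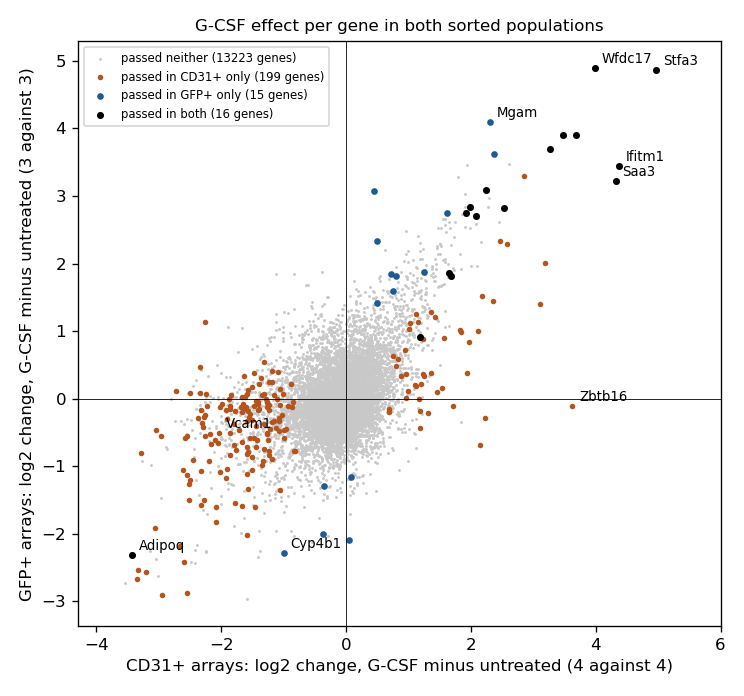
Log2 change after G-CSF in the CD31+ arrays (x axis) and in the GFP+ arrays (y axis), with 1 point per gene for 13453 genes, coloured by the populations in which limma called the gene. The 16 genes called in both, Ifitm1 and Adipoq among them, lie in the quadrants where both changes have the same sign.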

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

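The tests of dilution, scaling and carried-over GFP+ RNA, and those of neutrophil and marrow blood RNA, were chosen only after the result was seen. Groups of 4 arrays were searched for an array whose gap to the nearest other exceeds Dixon's 95% limit as a share of the range, for named genes and list means. Of 372 endothelial groups 28 held such an array, and chance picks about 1 in 20, or 18.6. The osteoblast groups of 3 were not searched.

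Of these 28, 11 fell on untreated endothelial replicate 2. It was low in the collagen list at 11.50 against 12.51 to 12.63 (ratio 0.887) and in the Wnt list (0.843), and in Col11a1 (0.858), Col11a2 (0.865), Phex (0.874), Irx5 (0.892), Creb3l1 (0.909) and Gng4 (0.866). It was high in the osteoclast marker list (0.900), Pecam1 (0.902) and Icam2 (0.860). Untreated replicate 4 was low in the monocyte list (0.891), Prok2 (0.897), Slfn4 (0.874), Cxcr2 (0.836) and Ptprc (0.846). Untreated replicate 1 was high in Sox10 (0.835) and untreated replicate 3 in Cxcl9 (0.888). G-CSF replicate 3 was low in the oxidative phosphorylation (0.855) and skeletal muscle (0.881) lists, Myh4 (0.856), Bnip3 (0.853), Klf6 (0.840) and Oas2 (0.8293), and high in Stab2 (0.840) and Prkdc (0.855). G-CSF replicate 4 was high in the erythroid list at 8.91 against 6.22 to 6.57 (0.872), and G-CSF replicate 2 in Icam2 (0.962).

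The test of the difference between populations called 9 lists with the preset correlation and 0 with an estimated one. Their median differences, with the range over each array left out, were 1.59 (1.17 to 2.04) for osteoblast function, 1.39 (0.75 to 1.91) for osteocyte, 1.04 (0.74 to 1.38) for collagen and 1.04 (0.72 to 1.23) for Wnt genes. They were 0.53 (0.28 to 0.75) for sinusoidal, 0.29 (0.08 to 0.49) for immediate early, 0.68 (0.20 to 1.74) for neutrophil, 1.13 (0.87 to 1.496) for fibroblast and tendon and 1.61 (0.32 to 2.24) for skeletal muscle genes.

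Osteoblast genes fell in the CD31+ arrays, at a median of -2.05 with 4 of 18 members called over all genes and 17 adjusted over the list alone (adjusted p = 0.24 with an estimated correlation), and the list shares Col1a1 and Col1a2 with the collagen list. A lower share of all cells that are not endothelial, alike for each kind, stays open. The mean changes of the neutrophil, monocyte, osteoclast marker, chondrocyte and fibroblast lists lay above that of the osteoblast list. The distances were 2.48 (SE 0.593), 2.06 (SE 0.702), 1.46 (SE 0.690), 1.27 (SE 0.598) and 1.16 (SE 0.460). These lists cannot decide, because G-CSF may itself raise neutrophil and monocyte genes, and endothelial cells may express some members. Ostm1 of the osteoclast marker list was higher in untreated CD31+ than in GFP+ arrays. Members with low signal, whose falls are understated, were not left out. The other 9 lists, erythroid (-0.68, SE 0.723), B lineage (0.13, SE 1.15) and skeletal muscle (0.06, SE 1.40) among them, lay within 2 SE of the osteoblast list. A lower share of only some kinds stays open too. These SE ignore the pairing by replicate number, and which lists lie within 2 SE may change with it. Scaling is argued against by the median of -1.89 after quantile normalisation. RNA of the GFP+ cells carried over in their own proportions stays open. The untreated difference between sorts had an SD of 1.46 over the list's genes, against a median SE of 0.574 for a gene. Genes near the top of the scale, Col1a1 among them, were kept in this test. Their difference may be narrowed there, which raises the SD under carry-over too, so the SD cannot decide. Fewer cells or less RNA of the osteoblast lineage in the CD31+ sort stays open: 116 genes outside the lists that were higher in untreated GFP+ arrays than in untreated CD31+ replicates 1 and 2 had a median change of -1.29 (quartiles -1.88 to -0.63) from untreated CD31+ replicates 3 and 4 to the 4 G-CSF arrays. Cells of that lineage that carry no GFP may be the source, as Col1a1 stood at 15.33 in untreated CD31+ arrays, but the gate on CD31 would remove them, and a fall within cells was not told apart from fewer cells.

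Among the 15 genes that rose in both populations, those known from myeloid cells include Stfa3, Prok2, Slfn4 and Wfdc17. The rest were not assigned to a cell type here. More neutrophils of an unchanged kind stay open: in the CD31+ arrays 15 members of the neutrophil list with levels up to 14 had a mean change of 0.84, which is -1.69 (SE 0.308) from the median of 2.53 of the 15 shared genes, but those genes were picked because they rose, so a lower list mean excludes nothing. RNA of marrow blood cells in both sorts stays open too, since over 83 genes of the blood cell lists the changes in the populations correlated with r = 0.922. The CD45 and ter119 gates would remove such cells where they carry either marker, yet S100a8 averaged 15.37 and Ngp 14.96 in untreated endothelial cells. Neutrophils with another expression state under G-CSF, or a response of the stromal cells themselves, were not tested.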

How the results depend on the processing

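Of the alternatives, those on 2 arrays that stood apart, decimals, export batch and actin and GAPDH ratios were chosen after the data were seen, and the others before. In the order higher and lower, counts of called genes were 25 and 6 in osteoblasts, 61 and 154 in endothelial cells, 0 and 0 for the difference and 1831 and 1722 between untreated populations, and lists 8 and 4, 5 and 13, 9 and 0, and 6 and 11. With an estimated correlation the lists were 1 and 0 in osteoblasts, 0 and 0 in endothelial cells, 0 higher for the difference and 0 and 0 between populations. With fry they were 1 and 0, 1 and 7, and 0 higher for the difference. A pseudocount of 64 gave 14 genes lower in osteoblasts. Quantile normalisation gave 39 and 68 genes and 3 lists higher in endothelial cells, and centring on the median 54 lower. The mean of a gene's probe sets, and all probe sets singly, gave 1 lower for the difference, and the latter 4569 and 2915 between populations, where it counts probe sets. Only the arrays compared gave 2 and 0 in osteoblasts and 240 higher in endothelial cells. The block within cell types gave 45 and 19, 139 and 521, and 1 lower for the difference, and the block across them 9 higher, 417 lower and 2 lower. Array weights gave 154 and 24 in osteoblasts and 344 and 685 in endothelial cells. An adjusted p under 0.01 gave 5 and 3, 13 and 14, and 1048 and 1068 between populations. Without the 2 arrays that stood apart, osteoblasts had 384 and 43, endothelial cells 91 lower, and the difference 1 gene and 14 lists higher. The decimals term gave 12 lower in osteoblasts. Osteoblasts of 1 export batch had 2 and 1 genes and 5 lists higher, the difference had 1 list lower, and the correlation of changes was 0.336. That list was cell cycle, which reversed to a median of -0.35. The actin ratio gave 43 higher in osteoblasts and 77 lower in endothelial cells, and the GAPDH ratio 42 and 85.

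With each array left out in turn, the lowest and highest counts in osteoblasts were 2 to 426 genes higher, 2 to 49 lower, 6 to 9 lists higher and 4 to 5 lower. In endothelial cells they were 13 to 65, 15 to 323, 3 to 6 and 11 to 13. For the difference they were 0 to 18, 0 to 3, 5 to 15 and 0 to 0, and between untreated populations 1283 to 2190, 1328 to 2351, 5 to 8 and 9 to 14. The correlation ran from 0.386 to 0.529. Of the 31 genes called in osteoblasts 29 were also called with the block within cell types, and of 215 in endothelial cells 212. Called genes kept in every alternative were 1 of 17 named in osteoblasts (Ifitm1), 11 of 40 in endothelial cells and 91 of 118 between populations. Over all alternatives, log2 changes of named genes were the same in call and direction in 8401 cases, lost a call in 554, gained a call in 150 and changed sign uncalled in 59. Lists did so in 2178, 205, 104 and 172 cases, with 1 reversed. The block changed no call of a named gene or list other than those given beside their results, and scaling ended or made calls of the unfolded protein, p53, monocyte, hypoxia, megakaryocyte, niche, BMP, endothelial identity, immediate early and pericyte lists. A block within cell types gives no value between populations, the difference uses all 14 arrays so that only the arrays compared was not run for it, and the thresholds do not apply to the correlation. The cause was not tested.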

Other observations

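The tests of dissociation stress, and the choice of the genes of this pattern, were made only after the result was seen. In the CD31+ arrays Zbtb16 rose by 3.62 on the log2 scale, Map3k6 by 2.23, Klf15 by 2.15, Dbp by 2.11, Fkbp5 by 1.54 and Tsc22d3 by 0.87, genes that glucocorticoids or the daily clock control. In osteoblasts their log2 changes were -0.10, -0.29, -0.69, 1.01, 0.16 and 0.33, and the adjusted p of the difference was at least 0.208.

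Dissociation stress is argued against by the immediate early list, whose mean change was 0.0740 (SE 0.153). A glucocorticoid response cannot be told apart from none, because a list of 13 further targets had a mean change of 0.143 (SE 0.214, exact permutation p = 0.514) but had left out genes already known to be called. Another time of day at collection stays open: over 8 clock genes, the change of those in the phase of Dbp minus those in the opposite phase was 1.42 (SE 0.355, exact permutation p = 0.0286, the smallest that 35 splits can give, but 0.125, the smallest of the 8 splits that keep the pairing by replicate number). In the phase of Dbp the log2 changes were 1.15 for Per2, 0.04 for Per3, 1.499 for Nr1d1, 1.06 for Nr1d2, 0.43 for Tef and 0.11 for Hlf, and in the opposite phase -0.42 for Arntl and -0.995 for Npas2, with adjusted p of at least 0.0627 for each. In osteoblasts these changes were, in the same order, 0.45, 0.39, 0.50, 0.38, -0.05 and 0.63, and -1.03 and 0.05. The unadjusted limma p of the difference between populations was at least 0.0864 for each, so a clock change particular to the CD31+ arrays was not shown. The groups may have been collected at different hours, which the labels do not give, or G-CSF may act on the clock of these cells, and the design does not separate these.

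Other splits of the same arrays, a planned test, were searched for as many called genes as the real one. In endothelial cells 1 of 35 splits, the real one, reached 215 genes and the highest other called 0. Between untreated populations 1 of 35 splits, the real one, reached 3553 and the highest other 1016. Chance is excluded over these 35 splits between the untreated populations. In endothelial cells the 35 splits ignore the pairing by replicate number, so chance is not excluded there. For the difference all 100 splits drawn reached the real count of 0, and the highest other called 6. Every split must reach 0, so this says nothing about chance. In osteoblasts 3 of 10 splits reached the 31 genes of the real split, itself included, so chance is not excluded. The 10 splits would also be too few to exclude it. The other 2 called 404 and 86. The split with 404 set untreated replicates 1 and 3 with G-CSF replicate 3 against the rest, and the split with 86 set them with G-CSF replicate 1. This points to structure of the samples, as untreated replicate 2 stood with the G-CSF arrays in neutrophil genes. Among the splits that part every pair of the same replicate number, 4 in osteoblasts and 8 in endothelial cells, the real ones called 31 and 215 and the others 0. Both numbers of splits are too few for a share under 0.05.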
